A study of Homo sapiens
Mus musculus and Mus musculus with 4 samples.

How the data were processed

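Nuclei from 15 frozen mouse specimens were profiled by sci-RNA-seq, a method that barcodes the RNA of single nuclei by splitting and pooling them. Per the labels, the mice lacked Ink4a/Arf and were injected in the brain as pups with RCAS-PDGFB, an avian retroviral vector carrying the growth factor gene PDGFB, which gives rise to gliomas. The specimens were the hemisphere holding the tumour or normal brain. They were taken without irradiation, about 8 hours after 10 Gy of X-rays, or about 72 hours after it. The labels do not say that the specimens came from separate animals. So a p-value of a gene or class share measures only the spread between these specimens. A mixture of equal parts human 293T and mouse NIH3T3 cells was sequenced with them to measure how often 2 cells shared a barcode.

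The values are UMI counts per gene and cell, and a UMI (unique molecular identifier) marks 1 captured RNA molecule. Per the labels and the deposited matrices, these counts were made by the authors before any step described here. Per the submitters' processing notes, the genome builds were hg19 and mm10. The same notes name bcl2fastq 2.16, Trim Galore 0.4.1, STAR 2.5.2b, bedtools 2.26.0 and Bowtie2 2.2.3. The step each tool served, the gene annotation and the filters on cells and genes are not given in the sources used here. Coordinates in the text are from GENCODE vM21 on mm10. Of 11758 gene identifiers in the mouse matrix, 11737 had a symbol there, and 10119 of these matched with the version number. Every gene of that matrix was seen in at least 79 cells, so rarer RNAs are not in it.

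The mouse matrix held 15648 cells and 18123723 UMIs, with a median of 558 UMIs per cell and a range of 17 to 23771. Each cell name holds a reverse transcription (RT) well, and a list of 191 RT wells assigned each specimen 12 wells, except 72 h brain 2, which had 11. The 4 libraries each mixed specimens, so a cell was given to its specimen by its well. Libraries 1 and 2, called pool A here, held 11 specimens and the species mixture. Libraries 3 and 4, called pool B, held unirradiated brain 2 and 3, 72 h brain 3 and 72 h tumour 2. No cell lay in a library whose labels do not list its specimen (0 cells). Depth differed strongly between specimens, from 12627 UMIs in 72 h brain 3 to 3678747 in 8 h tumour 1. Intervals on ratios and floors on folds cover the counting error alone.

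The groups, comparisons, tests and gene lists were fixed before the data were examined. UMIs were summed per specimen and compared with edgeR 4.0.16 in R 4.3.3. All 15 specimens entered 1 fit with 6 groups of tissue and time and a term for pool. Low genes were removed with filterByExpr on the groups, sizes were scaled by TMM, and the quasi-likelihood test was used with Benjamini-Hochberg adjustment at 0.05. The comparison of tumour with brain took the mean of the 3 tumour groups minus the mean of the 3 brain groups. The test of a difference between tissues took the time effect in tumour minus the time effect in brain. The fit had 8 residual degrees of freedom and a common dispersion of 0.108. Values in CPM (UMI counts scaled to a common total) are means per specimen with standard deviations, whereas fold changes come from the fit and are given with a standard error (SE). DESeq2 1.42.0 with the same genes and design was the first alternative.

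A fold against a group with 0 UMIs is given as a lower bound, computed as if that group held 3 counts. Where a group held 1 to 3 UMIs, the ratio of pooled counts is given with its 95% counting interval.

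Cell classes were rebuilt, since a class label per cell was not used here. Cells with at least 500 UMIs (8330) were clustered by Leiden in leidenalg at resolution 1, on 2000 variable genes, 30 components and 15 neighbours. This gave 28 clusters, and resolutions 0.5 and 2 were alternatives. A cluster took a class when at least 3 markers and a share of at least 0.5 of its list stood at 0.25 or more of the highest cluster's CPM. A cluster stayed unnamed when its leading genes held more markers of another class than of its own. Genes counted as leading only if seen in a share of at least 0.1 of its cells. The other 7318 cells were given a class from the clusters' profiles by a multinomial model at a posterior of 0.9. When 2000 deep cells were thinned to 150 UMIs, 98.6% were assigned and 99.2% of these kept their class. Clusters 1, 11, 21 and 26 carried the markers of oligodendrocyte progenitor cells (OPC), which the tumour cells of this model share. With the cycling cluster 15 they formed the OPC/tumour-like class.

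The clusters behind that class differed between groups. Cluster 1 held 84.2% of the class in 8 h tumours, cluster 11 held 76.6% of it in 72 h tumours, and cluster 26 held 43.8% of it in unirradiated tumours. In brain, cluster 11 held 36.1% of the class without irradiation, 93.2% at 8 h and 86.7% at 72 h. These shares pool the cells of a group, and some clusters came mostly from 1 specimen. Among cells with at least 500 UMIs, 8 h tumour 1 gave 90.6% of cluster 1 and 72 h tumour 1 67.2% of cluster 11. Unirradiated tumour 3 gave 90.4% of cluster 21, and unirradiated tumour 1 gave 74.6% of cluster 26. So a difference between groups in these clusters can be one between specimens. Clusters 16, 18, 19 and 24 were the differentiating oligodendrocyte-like, oligodendrocyte-like, microglia/macrophage-like and astrocyte-like classes. Clusters 8, 23 and 27 stayed unnamed, and the rest were neuron-like. Cells in unnamed clusters made up 0.891%, 1.29% and 8.53% of brain cells without irradiation, at 8 h and at 72 h, and 7.95%, 5.14% and 9.45% of tumour cells. Cluster 8 carried neuron markers, but its leading genes held 0 markers from the neuron lists and 1 of another class. Of its cells, 72.2% came from 72 h tumour 1.

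Doublets were scored with Scrublet through Scanpy 1.11.5 at an expected rate of 0.08 in cells with at least 100 UMIs. It called 289 of 13282 cells in pool A and 1 of 1883 in pool B, and all were kept in the main analysis. Class shares are shares of all cells given to a cluster, those of unnamed clusters included. Tumour and brain shares were compared by an exact two-sided permutation test over 6435 splits, and the times within a tissue by edgeR on cell numbers with total cells as offset. Genes were compared within a class across specimens with at least 20 cells of it. The OPC/tumour-like fit used tumour specimens alone, and the other class fits held terms for time, tissue and pool. Astrocyte-like cells were too few to compare (fewer than 20 cells in most specimens).

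Lists of genes written from general knowledge before the data were examined covered p53 targets, the G2/M and S phases, double-strand break repair, stem-like cells, OPC identity, myelin and oligodendrocyte maturation, mesenchymal and proneural glioma, the interferon response, NF-kB and inflammation, immediate early genes, the glucocorticoid response, hypoxia, synapses and heat shock. Marker lists for cell types were treated the same way, and lists with fewer than 3 tested members were not tested. Lists were tested with limma 3.58.1 by camera at its preset correlation of 0.01, with adjustment over lists. Camera sets the genes of a list against the other genes tested. At a fixed correlation its p-value therefore does not measure how far a list varies between specimens. The lists were tested again with an estimated correlation and by fry. Members were also counted after adjustment over all genes and over the list alone.

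Named genes were picked by rule. From each comparison the 10 largest increases and 10 largest decreases are named among genes that passed, reached 20 CPM in the higher group and did not overlap between the groups. Up to 4 members of each list with the smallest p are named as well, and where nothing passed, the 5 genes with the smallest p are given as not passing. The share of genes without overlap that chance gives holds for genes not selected by a test, so it does not support the calls beside it. Gene models without a name were counted, and named only where few genes passed. For each gene with at least 20 UMIs in a specimen, a check asked whether more than 50% of them came from 1 RT well that held less than 25% of the specimen's UMIs. It listed 119 genes in 149 of 78847 pairs of gene and specimen, called single-well genes below. This check was chosen after the first results were seen.

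The edgeR steps were tested on simulated data in which only more highly expressed genes were given 4-fold changes. They recovered 61.5% of 200 changed genes in the fit of whole specimens with 1.6% false calls, and 74.0% with 4.5% false calls in OPC/tumour-like cells. Recovery was 100% in neuron-like cells, 90.4% of 104 genes in oligodendrocyte-like cells and 92.5% of 40 genes in microglia/macrophage-like cells. False calls there were 4.3%, 6.9% and 5.1%. Alternatives covered the test, size scaling, filter, pool term, doublets, cluster resolution and each specimen left out, and the closing section gives their effect. Group labels were also swapped between specimens in up to 100 splits for some comparisons. These were tumour against brain, the same without irradiation, brain at 72 h, and neuron-like and oligodendrocyte-like cells at both times. The other comparisons, tumour at 8 h among them, had no such splits. Cells of the species mixture were called by at least 90% of UMIs from 1 species. Work in Python 3.11.15 used numpy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.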

Results

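The data were nuclei of 15 mouse specimens from an RCAS-PDGFB glioma model, in which a virus carrying PDGFB starts tumours in Ink4a/Arf-deficient mice. There were 3 unirradiated tumours, 2 tumours at 8 h and 2 at 72 h after 10 Gy, and 3, 2 and 3 normal brains at the same times. Tumours held 1340, 309 and 851 cells without irradiation, 3218 and 1089 at 8 h, and 1489 and 483 at 72 h. Brains held 671, 500 and 887 cells without irradiation, 1570 and 441 at 8 h, and 957, 1753 and 90 at 72 h. Median depth ran from 119.5 UMIs per cell in 72 h brain 3 to 1847 in 8 h brain 2. Unirradiated brains held 1074005, 120997 and 352000 UMIs, 8 h brains 3512209 and 1130075, and 72 h brains 2354295, 1060839 and 12627. Unirradiated tumours held 285999, 95688 and 1382695 UMIs, 8 h tumours 3678747 and 372858, and 72 h tumours 2589434 and 101255.

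Cdkn2a, the gene of the Ink4a/Arf locus deleted by design, gave 10, 7 and 32 UMIs in unirradiated tumours, 441 and 66 in 8 h tumours, and 57 and 0 in 72 h tumours. Brains gave 1, 0 and 0 UMIs without irradiation, 2 and 1 at 8 h, and 5, 1 and 0 at 72 h. In 8 h tumours this was 120 and 177 CPM (UMI counts scaled to a common total), against 35.0, 73.2 and 23.1 CPM without irradiation. Which part of the locus was deleted, and where in the gene these UMIs lie, were not examined. So these counts check neither the deletion nor the protein. Xist, the RNA of the inactive X chromosome, gave 3117 UMIs in 8 h tumour 1, 26 in 72 h tumour 2 and 2 in 72 h brain 3. The first of these held 11 UMIs of Y-linked genes and the other 2 held 0, so 3 specimens were female by this measure. For 72 h brain 3, which held 12627 UMIs in all, that rests on few UMIs and is uncertain.

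The first question was how the cell types of the tumour-bearing hemisphere differ from those of normal brain. OPC/tumour-like cells made up 50.4% of the cells given to a cluster in tumours (SD 35.7, n = 7) and 2.87% in brains (SD 1.51, n = 8). Neuron-like cells made up 34.8% (SD 34.7) and 83.4% (SD 9.03). Both differences passed an exact two-sided permutation test, at adjusted p = 0.00839 and 0.0112. Oligodendrocyte-like cells stood at 1.53% and 4.95% (adjusted p = 0.0911 by the same exact permutation), and did not pass. They passed with pool A alone, at 1.68% and 7.06% (adjusted p = 0.0217 by that permutation), and without 72 h brain 3 (0.0361), and over all alternatives the adjusted p ran up to 0.174. Astrocyte-like cells stood at 0.854% and 2.01% (0.352 by the exact permutation). Differentiating oligodendrocyte-like cells stood at 1.71% and 0.746%, and microglia/macrophage-like cells at 3.07% and 2.21% (0.665 for each by the exact permutation). The tumours varied widely, and the OPC/tumour-like share ran from 0.208% in 72 h tumour 2 to 92.5% in an unirradiated tumour.

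**Figure D1:**
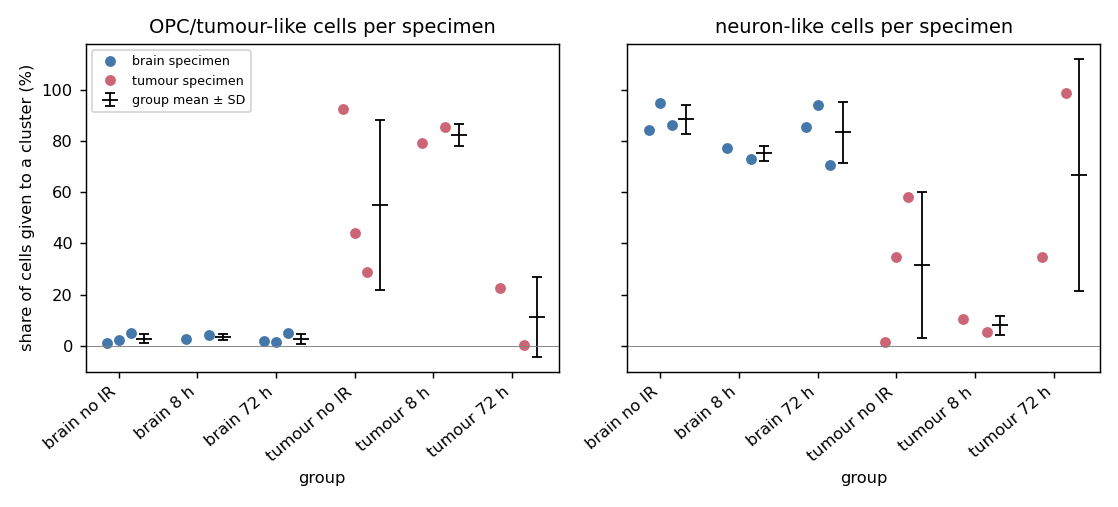
Share of OPC/tumour-like and of neuron-like cells per specimen. OPC/tumour-like cells averaged 50.4% in 7 tumours and 2.87% in 8 brains.

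By time, OPC/tumour-like cells made up 55.2% of unirradiated tumours (SD 33.2, n = 3), 82.5% at 8 h (SD 4.26, n = 2) and 11.3% at 72 h (SD 15.7, n = 2). Neuron-like cells made up 31.4%, 7.94% and 66.8% of the same groups. In brain, OPC/tumour-like cells made up 2.73%, 3.35% and 2.68%, and neuron-like cells 88.6%, 75.3% and 83.5%. Oligodendrocyte-like cells were 4.16%, 8.36% and 3.45% of brain, and microglia/macrophage-like cells 1.58%, 5.25% and 0.808%. By edgeR's quasi-likelihood test on cell numbers with Benjamini-Hochberg adjustment, 0 of 24 share changes after irradiation passed, with a lowest adjusted p of 0.307. Without 72 h tumour 1, 1 passed. The 2 tumours at 72 h had 22.4% and 0.208% OPC/tumour-like cells, so any 72 h change in whole tumours mixes a change of cells with a change within cells.

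Genes of the glial progenitor lineage and of the cell cycle were among those that differed between whole tumours and whole brains. Ccnd1 (chr7:144929931-144939925), which encodes cyclin D1 and drives entry into the cell cycle, rose from 2.75 CPM (SD 2.11, n = 8) to 185 CPM (SD 158, n = 7). Its log2 fold change was 4.86 (SE 0.46, adjusted p = 9.36e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Prrx1 (chr1:163245119-163313710), a homeobox transcription factor gene, rose by log2 3.58 (SE 0.32, adjusted p = 8.21e-06 by edgeR). Pdgfra (chr5:75152292-75198215), which encodes a receptor for the PDGFB ligand and marks OPCs, rose by log2 4.90 (SE 0.75), from 25.8 to 370 CPM. Mki67 (chr7:135689784-135716361), a marker of dividing cells, rose by log2 6.34 (SE 0.83), from 1.09 to 85.5 CPM. Mobp (chr9:120149707-120181484), which encodes a myelin protein of mature oligodendrocytes, fell by log2 2.00 (SE 0.32), from 81.0 to 22.4 CPM.

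Among 11528 genes tested, edgeR called 1445, of which 896 rose and 549 fell, and DESeq2 called 1719. Of the called genes, 67 did not overlap between the 7 tumours and the 8 brains, where 0.0311% of unselected genes would by chance. Besides Ccnd1 and Prrx1, the largest increases in that group were Clic1 (log2 5.04, SE 0.75), a chloride channel gene, Cd63 (3.85), a gene for a membrane protein of late endosomes, and Gsap (3.36). They were followed by Sema5b (3.24), a semaphorin gene, Itga1 (3.10), an integrin gene, and Rhoj (3.10), a gene for a small GTPase. Phlda1 (2.90) and Amz1 (2.81) came next. The largest decreases after Mobp were Prmt8 (-1.93), a methyltransferase gene of neurons, Drc3 (-1.70), Mical2 (-1.63), Vipr1 (-1.55) and Kcnj6 (-1.46). Kcnj6 encodes a potassium channel of neurons, and Vipr1 a receptor for a neuropeptide. Camk4 (-1.44), Dync1i1 (-1.22), Plekhg5 (-1.18) and Sh3gl2 (-1.11) completed the named decreases. The call depended on 2 specimens, each the only pool A specimen of its group. Leaving either out puts its group wholly in pool B, so the pool term can also play a part. Without unirradiated brain 1 the count was 0, and without 72 h tumour 1 it was 4. Prrx1 and Mobp passed without every specimen but unirradiated brain 1 (adjusted p = 0.0714 and 0.0770 by edgeR without it), and without that specimen Ccnd1 and Pdgfra did not pass either. Without unirradiated tumour 3 the count was 2913.

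By list, 11 of 13 genes of OPC identity rose and 12 did after adjustment over the list alone, with a median log2 fold change of 3.02. Sox10 (log2 3.74), a transcription factor gene of the oligodendrocyte lineage, Cspg4 (3.95), which encodes the NG2 proteoglycan of OPCs, and Megf11 (2.84) were among them. The list passed by camera at adjusted p = 1.04e-11 (adjusted p = 0.151 with an estimated correlation). Of 8 proneural glioma genes 6 rose (8 adjusted over the list alone), among them Nkx2-2 (4.45) and Olig2 (2.77), 2 transcription factor genes of the same lineage. That list had a median of 2.25 and adjusted p = 1.28e-06 by camera (adjusted p = 0.151 with an estimated correlation). Of 13 G2/M genes 12 rose (12 adjusted over the list alone), with a median of 2.47. They included the mitotic genes Knl1 (2.53), Kif11 (3.21) and Aspm (4.33), and the adjusted p by camera was 5.80e-08 (adjusted p = 0.151 with an estimated correlation). Of 9 S phase genes 2 rose, Tyms (2.51) and Brip1 (2.27), and 6 did after adjustment over the list alone. Its median was 0.77, with adjusted p = 0.000396 by camera (adjusted p = 0.151 with an estimated correlation).

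Of 10 mesenchymal glioma genes 7 rose (8 adjusted over the list alone), with a median of 2.08. Vim (3.74), which encodes an intermediate filament, Tnfrsf1a (5.30), a TNF receptor gene, Stat3 (2.19) and Fn1 (4.09) were among them. The list passed at adjusted p = 5.28e-06 by camera (adjusted p = 0.151 with an estimated correlation). Of 10 stem-like genes 5 rose (7 adjusted over the list alone), among them Notch1 (3.09) and Cd44 (3.60), with a median of 2.33 and adjusted p = 0.000256 (adjusted p = 0.181 with an estimated correlation). Of 15 interferon response genes 12 rose (13 adjusted over the list alone), with a median of 2.28. B2m (2.28) and H2-K1 (2.64), genes of antigen presentation, and Oasl2 (5.03) were among them, and the adjusted p was 2.51e-09 (adjusted p = 0.151 with an estimated correlation). Of 21 p53 targets 7 rose (11 adjusted over the list alone), led by Pvt1 (1.92) and Eda2r (4.07), with a median of 0.95 and adjusted p = 1.19e-05 (adjusted p = 0.151 with an estimated correlation). Of 5 immediate early genes 2 rose, Fos (2.87) and Jun (2.38), and the same 2 adjusted over the list alone. That list had a median of 0.98 and adjusted p = 0.0310 by camera (adjusted p = 0.229 with an estimated correlation; 0.0589 by camera without a pool term).

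Camera passed genes of synapses and myelin downward in tumours. Of 15 synaptic genes 3 fell, Camk2a (-1.56), Grin2a (-1.60) and Snap25 (-1.16), and 8 fell after adjustment over the list alone. The median was -0.77, with adjusted p = 2.50e-06 by camera (adjusted p = 0.229 with an estimated correlation). These 3 genes passed less steadily, and Grin2a and Snap25 kept their call in only 4 of 15 fits with a specimen left out. Of 13 myelin genes 5 fell and 1 rose (8 and 1 adjusted over the list alone). Mal (-2.13) and Mog (-1.92), genes of the myelin sheath, fell with Mobp, whereas Bcas1 (2.45), which marks oligodendrocytes that start to myelinate, rose. The median was -1.02, with adjusted p = 0.000119 by camera (adjusted p = 0.151 with an estimated correlation). The sign of Bcas1 turned to -0.80 when a specimen was left out.

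The remaining lists did not pass by camera. Double-strand break repair had a median of 0.22 (adjusted p = 0.305), where Brca1 (2.40) rose and Prkdc (-1.65), a single-well gene, fell. Heat shock had a median of 0.17 (adjusted p = 0.278 by camera). Hypoxia had a median of 0.51 (adjusted p = 0.0517 by camera), where Vegfa (2.57), a gene for a vessel growth factor, and Slc2a1 (1.70), a glucose transporter gene, rose. NF-kB and inflammation had a median of 0.35 (adjusted p = 0.0994 by camera), where Icam1 (4.09) rose. The glucocorticoid response had a median of -0.02 and a mean of 0.62 (adjusted p = 0.790 by camera), where Mt2 (3.71), Cdkn1a (2.11) and Mt1 (2.53) passed upward and Zbtb16 (-1.11) downward. The sign of Cdkn1a turned to -0.36 when a specimen was left out, and it kept its call in 12 of 15 such fits. Zbtb16 kept its call in only 4 of 15, and did not pass by DESeq2 (adjusted p = 0.0584).

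Markers of other cell types moved with the groups. Among marker lists, excitatory neuron genes had a median of -1.01 (adjusted p = 4.02e-05 by camera; adjusted p = 0.178 with an estimated correlation). Oligodendrocyte genes had a median of -1.03 (adjusted p = 1.03e-05; adjusted p = 0.171 with an estimated correlation), and pan-neuronal genes -1.10 (adjusted p = 5.66e-05; adjusted p = 0.283 with an estimated correlation). Cycling markers had a median of 2.53, differentiating oligodendrocyte markers 1.96 and microglia markers 0.70 (adjusted p = 3.07e-08, 0.00251 and 0.00666 by camera). With an estimated correlation their adjusted p values were 0.171, 0.326 and 0.326. Astrocyte markers had a median of 0.71, inhibitory neuron markers -0.54 and striatal spiny neuron markers 0.60, and did not pass (adjusted p = 0.131, 0.110 and 0.531 by camera).

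The same question asked of unirradiated specimens alone left 1 gene that passed outside the single-well genes. Ccnd1 rose from 2.51 CPM (SD 2.90, n = 3) to 214 CPM (SD 160, n = 3), a log2 fold change of 5.71 (SE 0.94, adjusted p = 0.0321, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Sox10 stood at 125 and 3.46 CPM (log2 4.47, adjusted p = 0.238 by edgeR), and Pdgfra at 523 and 6.92 CPM (log2 5.73, adjusted p = 0.267 by edgeR), and neither passed. H2-K1 stood at 58.1 and 14.9 CPM (log2 3.21, adjusted p = 0.238 by edgeR), which did not pass. EdgeR called 4 genes, and 1128 had an unadjusted p under 0.05, whereas DESeq2 called 130. The other 3 called genes were Kyat3 (-5.09), Hsf2bp (-6.93) and 4930579P08Rik (-9.54), all single-well genes high in unirradiated brain 1. Only Ccnd1 did not overlap between the groups, where 10.0% of unselected genes would by chance. Its call was lost without unirradiated brain 1 or 2 or unirradiated tumour 2 (highest adjusted p = 0.786 by edgeR). It was lost as well when single-well genes were left out, which gave 0 genes. Without unirradiated tumour 3 the count was 979.

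By list without irradiation, camera passed OPC identity (median log2 3.00, adjusted p = 2.10e-07), proneural glioma (3.01, adjusted p = 2.51e-06), the interferon response (adjusted p = 6.50e-07) and synaptic genes (adjusted p = 6.50e-07). With an estimated correlation the adjusted p of each was 0.286. After adjustment over the list alone, 8 OPC identity, 7 proneural and 3 interferon response genes rose. No member passed over all genes (0 in each of these lists), and all 15 synaptic genes were lower. Stem-like genes (median 2.14), mesenchymal glioma genes (2.04) and G2/M genes (1.70) were higher too, with adjusted p = 0.00205, 0.00662 and 0.000765 by camera and 0.286, 0.315 and 0.298 with an estimated correlation. Immediate early genes (2.19), hypoxia (1.06), heat shock (0.70) and S phase genes (0.56) had adjusted p = 0.0170, 0.0164, 0.0190 and 0.0190 by camera, and between 0.286 and 0.297 with an estimated correlation. Without a pool term the first 3 of these did not pass (adjusted p = 0.225, 0.126 and 0.786 by camera). Camera also passed markers of neurons in general (-1.24) and of excitatory neurons (-1.01) downward and astrocyte markers (1.70) upward (adjusted p = 7.06e-05, 0.000526 and 0.00637), each at adjusted p = 0.273 with an estimated correlation. The p53 list stood at a median of -0.04 and did not pass (adjusted p = 0.756 by camera).

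In tumours 8 h after irradiation, targets of the transcription factor p53 rose. Eda2r (chrX:97333840-97377216), which encodes a receptor induced by p53, rose from 5.14 CPM (SD 7.69, n = 3) to 185 CPM (n = 2). Its log2 fold change was 5.45 (SE 0.63, adjusted p = 0.00133, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Trp53inp1 (chr4:11156431-11174379), a p53-induced gene tied to cell death and autophagy, rose by log2 3.97 (SE 0.54, adjusted p = 0.00133 by edgeR). Apaf1 (chr10:90989311-91082770), which encodes the core of the apoptosome, rose to 193 CPM, by log2 3.05 (SE 0.43, adjusted p = 0.00170 by edgeR). Pidd1 (chr7:141438113-141444025), a p53-induced gene for a death-domain protein, gave 179 UMIs against 0 and rose at least 26.0-fold (adjusted p = 0.00271 by edgeR).

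Of 21 p53 targets tested, 20 had a positive fold change, 9 passed over all genes and 16 passed after adjustment over the list alone. The median log2 fold change was 2.14, and with bounds for genes at 0 it was 2.14. The list passed by camera at adjusted p = 3.67e-41, and at adjusted p = 0.000737 with an estimated correlation. Besides Eda2r, Trp53inp1 and Apaf1, Ercc5 (2.40), a gene of nucleotide excision repair, Polk (2.98), a gene for a translesion polymerase, and Psrc1 (3.42) rose. Mdm2 (2.03), whose protein marks p53 for breakdown, and Ccng1 (2.64), a cyclin G gene, rose as well. Sesn2, a sestrin gene, gave 162 UMIs against 3, a ratio of 23.5 (95% counting interval 7.90 to 115, adjusted p = 0.0135 by edgeR). Cdkn1a, which encodes the cell-cycle inhibitor p21, stood at 116 against 16.1 CPM (log2 3.00, adjusted p = 0.108 by edgeR), and Fas (4.43) and Pvt1 (1.95) had adjusted p = 0.0934 by edgeR, so none of the 3 passed. Sesn1 (-0.47) was the member with a negative value.

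**Figure D2:**
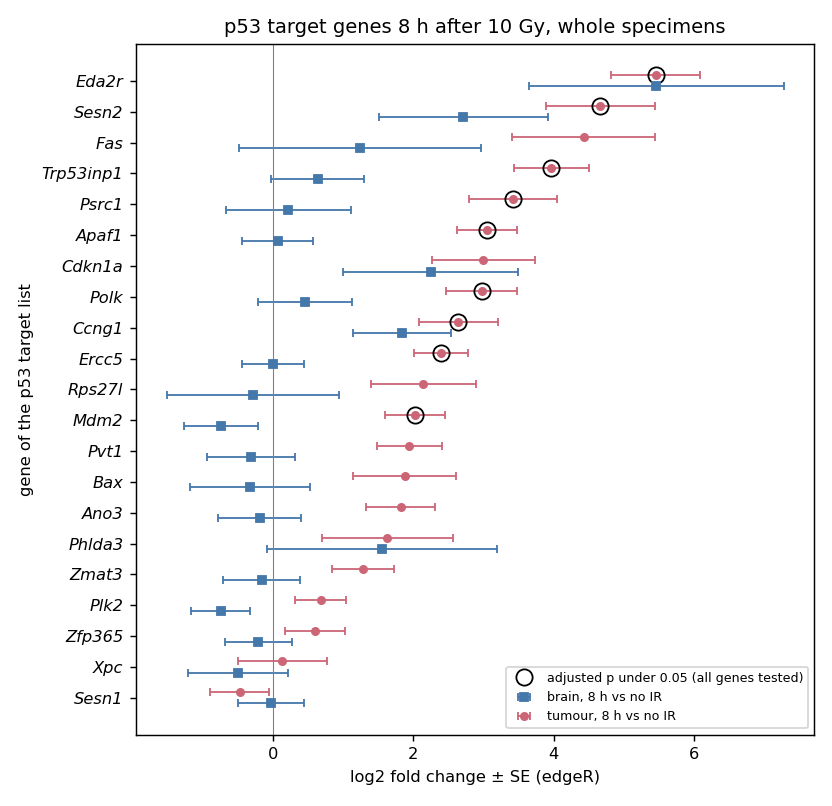
Log2 fold change of the tested p53 targets in 8 h tumours against unirradiated tumours. The median was 2.14, and 20 of 21 values were positive.

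EdgeR called 38 genes at 8 h, all of them up, and DESeq2 called 80, of which 36 were among the 38. A fit of only the 2 groups compared called 0. Of these 38, 36 did not overlap between the 2 and 3 specimens, where 20% of unselected genes would by chance. Beyond the list, Cd109 (4.29, SE 0.58), a gene for a surface antigen, Trp53cor1 (4.18), which gives rise to the p53-induced lincRNA-p21, and Ckap2 (4.24), a spindle gene, rose. Tshr, a hormone receptor gene, gave 188 UMIs against 3, a ratio of 27.3 (9.20 to 134), and Alox5, a lipoxygenase gene, 113 against 1, a ratio of 49.2 (8.65 to 1961). Ptprv, a phosphatase gene, gave 72 UMIs against 1, a ratio of 31.4 (5.45 to 1255). Mgmt (3.73), a DNA repair gene, Rad51b (2.76), a gene of homologous recombination, Map3k20 (3.39), a stress kinase gene, Adamtsl1 (3.27), Hmga2 (3.01), Exoc4 (2.41) and Angpt2 (2.85) also rose. Xist gave a ratio of 1357 (243 to 53631), since 8 h tumour 1 was female, and Clybl was a single-well gene. Map3k20, Apaf1, Tshr, Trp53inp1, Exoc4, Eda2r, Cd109 and Adamtsl1 passed without each of the 5 specimens.

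Single specimens moved the count strongly. It was 20 without 8 h tumour 1 or 8 h tumour 2, and 22 and 21 without unirradiated tumour 2 and 3. Without unirradiated tumour 1 it was 1194, with all 38 among them. Polk lost its call without 8 h tumour 1 (adjusted p = 0.0886 by edgeR), Ercc5 without 8 h tumour 2 (adjusted p = 0.0561 by edgeR) and Pidd1 without unirradiated tumour 3 (adjusted p = 0.0522 by edgeR). Mdm2, Ccng1, Ckap2, Alox5 and Ptprv passed in 1 of the 5 fits with a specimen left out, and Trp53cor1 in 2.

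Other lists moved less at 8 h. All 13 G2/M genes were higher (median log2 1.82), 0 passed over all genes and 2 over the list alone, with adjusted p = 4.97e-05 by camera (adjusted p = 0.399 with an estimated correlation). Tpx2 (3.01, adjusted p = 0.243 by edgeR) and Kif15 (2.19, adjusted p = 0.278 by edgeR), genes of the mitotic spindle, led it without passing. Mesenchymal glioma genes had a median of 0.98 (0 over all genes, 1 over the list alone), with adjusted p = 0.000489 by camera (adjusted p = 0.399 with an estimated correlation). Runx1 (2.37), a transcription factor gene, led it without passing. Double-strand break repair had a median of 0.62 (adjusted p = 0.00566 by camera; adjusted p = 0.399 with an estimated correlation), with Polq at 1.57, and no member passed. Immediate early genes had a median of 0.54 (adjusted p = 0.0394 by camera; adjusted p = 0.399 with an estimated correlation), and Fos (2.51) and Jun (2.32) passed over the list alone. Hypoxia (0.66) and OPC identity (0.36) both had adjusted p = 0.0411 by camera (adjusted p = 0.430 and 0.589 with an estimated correlation). Synaptic genes were lower, with a median of -0.95 (adjusted p = 0.00216 by camera; adjusted p = 0.522 with an estimated correlation), beside astrocyte markers (-0.57) and pan-neuronal markers (-1.10), with adjusted p = 0.0101 and 0.0113 by camera and 0.497 and 0.526 with an estimated correlation.

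At 72 h no gene passed in tumours (n = 2 and 3). EdgeR called 0 genes, 684 had an unadjusted p under 0.05, and DESeq2 called 16. The smallest p values fell on Abi3bp (68.3 against 10.8 CPM, log2 3.46), an extracellular matrix gene, H2-K1 (2.12 against 58.1 CPM, log2 -3.75), a class I antigen presentation gene, and Hmga2 (6.37 against 249 CPM, log2 -4.25), a gene for a chromatin protein. Apobec1 (3.89) and Gm10800 (106 UMIs against 2) followed, and all 5 had an adjusted p of 0.144 by edgeR. Of the genes that rose at 8 h, Eda2r stood at log2 1.86 (adjusted p = 0.709) and Trp53inp1 at 1.13 (adjusted p = 0.908, both by edgeR). The p53 list had a median of 0.14 (adjusted p = 0.409 by camera). Without unirradiated tumour 3 the count was 383, and without unirradiated tumour 1 it was 38.

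Progenitor genes were lower at 72 h, as was the share of OPC/tumour-like cells. OPC identity had a median of -1.11 (adjusted p = 1.04e-05 by camera) and proneural glioma -1.91 (adjusted p = 5.00e-05), with adjusted p = 0.515 for both with an estimated correlation. With pool A alone, which leaves out 72 h tumour 2, OPC identity did not pass (adjusted p = 0.138 by camera) and proneural glioma did (0.00605). Pdgfra stood at 52.1 against 523 CPM (log2 -2.61), Ncan at -2.84 and Bcan at -2.74, both genes for brain proteoglycans, and none of the 3 passed. Heat shock genes had a median of -1.12 and stem-like genes -1.22 (adjusted p = 0.00805 and 0.00902 by camera; adjusted p = 0.515 for both with an estimated correlation). Hsp90ab1 (-1.61) and Hspa8 (-1.50), chaperone genes, passed over their list alone. Interferon response genes had a median of 0.26 and a mean of -0.13, and camera called them lower (adjusted p = 0.0382; adjusted p = 0.544 with an estimated correlation), so the signs differ. Without a pool term neither heat shock nor interferon response genes passed (adjusted p = 0.282 and 0.0553 by camera), and with pool A alone the latter stood at 0.942. Synaptic genes had a median of 0.65 (adjusted p = 0.000283 by camera; adjusted p = 0.544 with an estimated correlation; 0.155 with pool A alone). Camera passed markers of striatal neurons (1.35), excitatory neurons (0.56), neurons in general (0.81) and microglia (0.73) upward, with adjusted p = 6.81e-05, 0.00175, 0.000694 and 0.0226, and astrocyte markers (-1.33) downward (adjusted p = 0.000823). With an estimated correlation none of these markers passed (adjusted p = 0.198, 0.312, 0.369, 0.543 and 0.198 in that order).

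In normal brain, the genes that passed after irradiation in the fit of all specimens were single-well genes. At 8 h (n = 2 and 3) edgeR called 3 genes, all down, which were 4930579P08Rik (-10.62), Kyat3 (-6.52) and Hsf2bp (-9.03), with adjusted p = 0.000670, 0.00104 and 0.0101. At 72 h (n = 3 and 3) it called 4930579P08Rik (-10.23) and Kyat3 (-6.15), with adjusted p = 0.000898 and 0.00231. All 3 stood high in unirradiated brain 1, from 1 RT well, and without that specimen edgeR called 0 genes at each time. It also called 0 at 8 h without 8 h brain 1, and 0 at 72 h without 72 h brain 1. At 8 h 190 genes and at 72 h 207 genes had an unadjusted p under 0.05, and DESeq2 called 2 and 4, of which 1 and 2 were single-well genes. A fit of only the 2 groups compared called 34 genes at 8 h, of which 5 were single-well genes and 29 were not, and 5 at 72 h, of which 4 were.

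The p53 list did not pass in brain, with a median of 0.00 at 8 h and -0.16 at 72 h (adjusted p = 0.259 and 0.895 by camera). With pool A alone it passed upward at 8 h (adjusted p = 0.0309 by camera). Eda2r gave 29 UMIs against 0 at 8 h (at least 3.22-fold), Sesn2 gave 32 against 1, and Cdkn1a stood at 11.1 against 4.01 CPM (log2 2.25), and none passed by edgeR. All 13 myelin genes were higher at 8 h, with a median of 0.74 (adjusted p = 9.12e-06 by camera; adjusted p = 0.497 with an estimated correlation) and 0 past over all genes. Mbp, which encodes myelin basic protein, stood at 225 against 109 CPM (log2 1.20, SE 0.45), and Cnp, an enzyme gene of myelin, at 41.3 against 21.8 CPM. Oligodendrocyte markers had the same median of 0.74 (adjusted p = 3.74e-06 by camera; adjusted p = 0.200 with an estimated correlation). At 72 h microglia markers were lower (11 of 11, median -1.63, adjusted p = 7.47e-07 by camera; adjusted p = 0.512 with an estimated correlation). Synaptic genes were lower too (15 of 15, median -0.45, adjusted p = 0.0375 by camera; adjusted p = 0.983 with an estimated correlation), and hypoxia genes had a median of 0.34 (adjusted p = 0.0255; adjusted p = 0.983 with an estimated correlation). Without a pool term neither synaptic nor hypoxia genes passed (adjusted p = 0.232 and 0.186 by camera), and with pool A alone synaptic genes stood at 0.823.

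Whether irradiation acted differently in tumour and brain was tested as the difference of the 2 effects in whole specimens. OPC/tumour-like cells made up 82.5% of 8 h tumours and 3.35% of 8 h brains. A difference of effects between tissues can therefore also be one between cell types. At 8 h the p53 list passed, with a median difference of log2 2.01 and adjusted p = 1.14e-13 by camera (adjusted p = 0.00543 with an estimated correlation). No p53 target passed over all genes (0), and 9 passed over the list alone, among them Apaf1 (2.98, SE 0.66), Mdm2 (2.77) and Trp53inp1 (3.33). Over all genes edgeR called 0, with 502 at an unadjusted p under 0.05, and DESeq2 called 5. Without unirradiated tumour 1 the count was 195. The smallest p values outside the single-well genes fell on Adamtsl1 (3.57) and Eva1c (4.27, adjusted p = 0.275 by edgeR), which did not pass. At 72 h edgeR called 1 gene, 4930579P08Rik (9.95), a single-well gene, with 381 at an unadjusted p under 0.05, and DESeq2 called 2. That call was lost without most of the other specimens (0 without 72 h brain 1, 2 or 3), and without unirradiated tumour 1 the count was 6. Myelin genes differed at 8 h (median -1.59, adjusted p = 6.59e-05 by camera; adjusted p = 0.336 with an estimated correlation). Mesenchymal glioma (1.62), double-strand break repair (1.08), G2/M (1.59) and OPC identity genes (0.68) differed upward at 8 h, with adjusted p = 0.00288, 0.00362, 0.00951 and 0.0423 by camera. With an estimated correlation their adjusted p values were 0.530, 0.344, 0.743 and 0.853. OPC identity did not pass at 8 h without a pool term or with pool A alone (adjusted p = 0.274 and 0.676 by camera). Microglia markers differed at 72 h (2.25, adjusted p = 4.15e-06; adjusted p = 0.543 with an estimated correlation), and so did synaptic genes (1.02, adjusted p = 2.70e-05; adjusted p = 0.646 with an estimated correlation). Immediate early (-2.22), hypoxia (-1.34), proneural glioma (-1.49) and OPC identity genes (-0.82) differed downward at 72 h, with adjusted p = 0.0121, 0.0101, 0.0121 and 0.0412 by camera. With an estimated correlation the lowest of these was 0.646, and no member of any of these lists passed over all genes (0). Heat shock genes (-1.21) passed downward too (adjusted p = 0.025 by camera; adjusted p = 0.646 with an estimated correlation). With pool A alone synaptic (0.262), proneural (0.102) and OPC identity genes (0.314) at 72 h did not pass by camera, and without a pool term hypoxia (0.0895), immediate early (0.201) and heat shock genes (0.857) did not.

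Within OPC/tumour-like cells of the tumours at 8 h (n = 2 and 3), measured in the same specimens, 9 of 20 p53 targets passed upward. The list of them did not pass with an estimated correlation (adjusted p = 0.0634). The clusters compared differed too, since cluster 1 held 84.2% of the class in 8 h tumours and 30.7% in unirradiated tumours. Trp53inp1 rose from 15.1 CPM (SD 14.1) to 284 CPM (SD 4.68), by log2 3.74 (SE 0.51, adjusted p = 0.00196, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Eda2r rose by log2 4.28 (SE 0.54, adjusted p = 0.000950 by edgeR), Apaf1 by 3.46 (SE 0.48, adjusted p = 0.00196 by edgeR) and Polk by 3.31 (SE 0.48, adjusted p = 0.00290 by edgeR). Adcy2 (chr13:68620043-68999541), which encodes an adenylyl cyclase, rose from 4.58 to 279 CPM (666 UMIs against 3, a ratio of 38.0, counting interval 12.9 to 185, adjusted p = 0.000645 by edgeR). H2-K1 (chr17:33996017-34000347) fell by log2 2.66 (SE 0.55), from 169 to 21.8 CPM (adjusted p = 0.0421 by edgeR), and Aldoc (chr11:78322968-78327781), a glycolysis gene of glia, fell by 2.42 (SE 0.50, adjusted p = 0.0439 by edgeR).

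**Figure D3:**
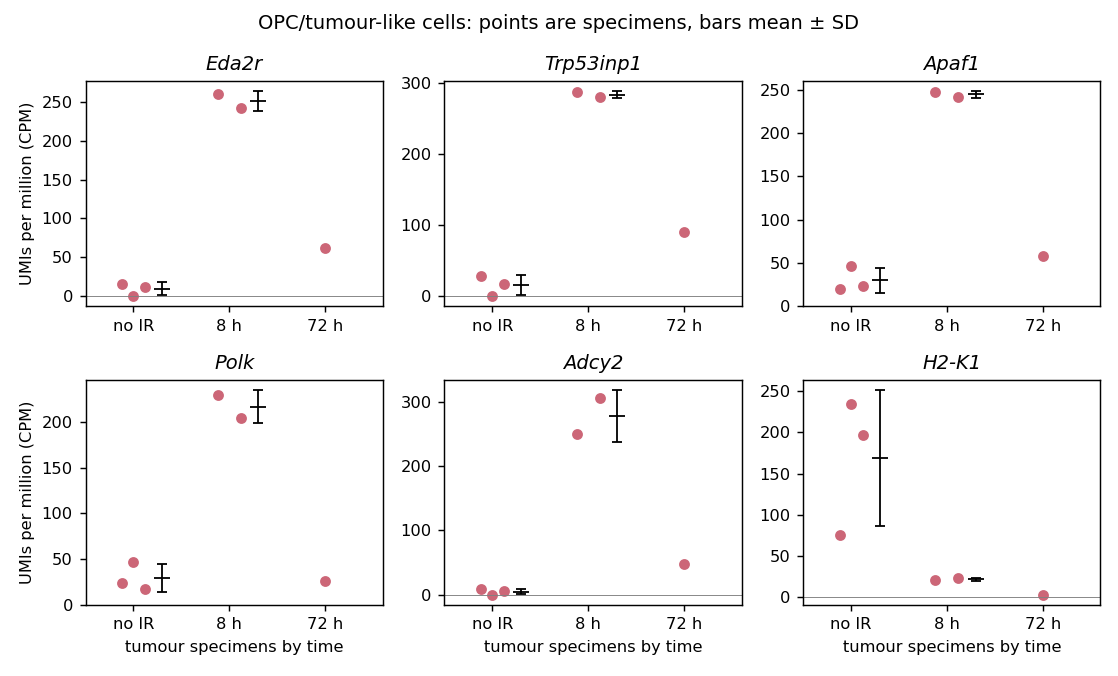
CPM of 6 genes in OPC/tumour-like cells per tumour specimen. Eda2r rose from 9.16 to 251 CPM at 8 h, and H2-K1 fell from 169 to 21.8 CPM.

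EdgeR called 31 genes of 7392 tested, 29 up and 2 down, and DESeq2 called 27. All 31 lay without overlap between the groups, where 20% of unselected genes would by chance. Psrc1 gave 272 UMIs against 0 (at least 15.5-fold), Tshr 171 against 0 (at least 9.75-fold) and Sesn2 144 against 0 (at least 8.21-fold). Hs3st4, a heparan sulfate enzyme gene, gave 352 against 1 (a ratio of 60.2, 10.7 to 2385), Dapk1, a death-associated kinase gene, a ratio of 39.2 (6.96 to 1554), and Mgmt 22.2 (6.10 to 185). Adamtsl1 (4.72) and Svop (4.41), a synaptic vesicle gene, also rose, with Foxo3 (2.21), Ano3 (2.68), Ccng1 (2.59) and Ercc5 (2.32). Cdkn1a stood at 153 against 17.9 CPM and did not pass (log2 2.49, adjusted p = 0.0835 by edgeR). Of the 38 genes of whole tumours, 21 were also called here. Without 8 h tumour 1 the count was 9, which kept Adcy2, Trp53inp1 and Eda2r but not Apaf1 or Polk, and without 8 h tumour 2 it was 18. Aldoc, Ccng1 and Sesn2 passed in 0 of the 5 fits with a specimen left out, and H2-K1 in 1.

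Of 20 p53 targets tested in this class, 19 had a positive fold change, 9 passed over all genes and 15 over the list alone. The median was 2.40, and with bounds for the 2 members at 0 it was 2.40. The list passed by camera at adjusted p = 2.38e-37 (adjusted p = 0.0634 with an estimated correlation). Interferon response genes were lower in 12 of 13 (median -0.82, adjusted p = 0.000246 by camera; adjusted p = 0.369 with an estimated correlation), with 1 past over all genes and 3 over the list alone. H2-D1 (-2.34, adjusted p = 0.126 by edgeR) and B2m (-1.49, adjusted p = 0.357 by edgeR) did not pass over all genes. G2/M genes had a median of 0.92 (adjusted p = 0.0438 by camera; adjusted p = 0.797 with an estimated correlation). Astrocyte markers (-0.70) and microglia markers (-1.57) were lower, with adjusted p = 0.00279 and 0.00603 by camera and 0.703 and 0.918 with an estimated correlation. OPC identity stood at -0.02 (adjusted p = 0.516 by camera).

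At 72 h only 72 h tumour 1 held enough OPC/tumour-like cells (332), so that lone specimen is assumed to vary like the others. In it cluster 11 held most of the class, which in 8 h tumours lay in cluster 1. EdgeR called 0 genes, 584 had an unadjusted p under 0.05, and DESeq2 called 8. Without unirradiated tumour 1 the count was 15, and without unirradiated tumour 3 it was 3. Igfbp3, a gene for a growth factor binding protein, gave 2 UMIs against 119, and Eml4 stood at log2 3.06, a single-well gene (adjusted p = 0.0771 for both by edgeR). Trp53inp1 stood at 90.4 CPM (log2 2.31, adjusted p = 0.278), Eda2r at 61.3 CPM (2.46, adjusted p = 0.315) and Apaf1 at 58.1 CPM (1.60, adjusted p = 0.548, all by edgeR). The p53 list had a median of 0.47 (adjusted p = 0.0102 by camera; adjusted p = 0.431 with an estimated correlation), with 0 past over all genes and 3 over the list alone. All 13 G2/M genes were higher (median 1.97, adjusted p = 2.36e-06 by camera; adjusted p = 0.591 with an estimated correlation). Hypoxia (-1.43), heat shock (-1.23) and stem-like genes (-0.89) were lower, with adjusted p = 0.00246, 0.0339 and 0.0298 by camera and 0.431, 0.431 and 0.591 with an estimated correlation.

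In neuron-like cells, few genes passed, and the clusters behind the class differed between groups. Clusters 9 and 12 held 30% and 25.7% of the class in 8 h tumours and 18% and 12.9% in 72 h tumours, against 4.4% and 1.3% in unirradiated tumours. In unirradiated brains they held 0.1% and 0.3%, so a change within the class is in part a change of its clusters. Among cells with at least 500 UMIs, 72 h tumour 1 gave 60.8% of cluster 9 and 48.7% of cluster 12. At 8 h (n = 4 and 5) Abi3bp (chr16:56477878-56690135) rose from 11.4 to 74.4 CPM (log2 2.52, SE 0.51, adjusted p = 0.0474, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Drd2, a dopamine receptor gene of striatal neurons, rose at a ratio of 59.4 (counting interval 10.5 to 2364, adjusted p = 0.0229 by edgeR), and Gm26870 at a ratio of 28.9 (4.99 to 1162). Kyat3, Tug1 and Lrmda fell and were single-well genes. Tug1, a long noncoding RNA gene, fell by log2 2.45 and kept its call in 9 of 9 fits with a specimen left out, whereas Kyat3 lost it without unirradiated brain 1. Of the 6 called genes 3 lay without overlap, where 1.59% of unselected genes would by chance, and DESeq2 called 0. The count ran from 2 without unirradiated tumour 3 to 14 without unirradiated brain 1. Striatal markers were higher (adjusted p = 5.39e-05 by camera; adjusted p = 0.153 with an estimated correlation). The p53 list had a median of 0.26 (adjusted p = 0.0445 by camera; adjusted p = 0.510 with an estimated correlation), with 0 past over all genes and 2 over the list alone. Synaptic genes were lower in 15 of 15 (median -0.26, adjusted p = 0.000202 by camera; adjusted p = 0.485 with an estimated correlation). OPC identity genes stood at 0.73 (adjusted p = 0.000109 by camera, 0.243 with an estimated correlation). Glucocorticoid response genes stood at -0.53 (adjusted p = 0.0111 by camera, 0.243 with an estimated correlation). Whether free RNA from other cells played a part in the OPC identity and p53 values was not tested.

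At 72 h (n = 5 and 5) neuron-like cells gave 6 called genes, and DESeq2 called 3. The count was 11 without unirradiated brain 1, 10 without 72 h brain 2 and 13 without 72 h tumour 2. The 3 that rose were Gm26870 (363 UMIs against 1, a ratio of 201, 35.8 to 7948), Gm10801 (188 against 0, at least 34.6-fold) and Gm10800 (179 against 2, a ratio of 49.5, 13.5 to 412). All 3 are gene models without an assigned name. Kyat3 (-5.24), Tug1 (-1.71) and Lrmda (-3.39), the 3 that fell, were single-well genes. Myelin genes had a median of 0.80 (adjusted p = 0.000818 by camera; adjusted p = 0.421 with an estimated correlation) and striatal markers 1.25 (adjusted p = 0.000274; adjusted p = 0.360 with an estimated correlation). Oligodendrocyte markers stood at 0.83 (adjusted p = 0.000274; adjusted p = 0.360 with an estimated correlation), and synaptic genes at -0.12 (adjusted p = 0.0417 by camera; adjusted p = 0.810 with an estimated correlation).

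Microglia/macrophage-like cells gave 3 called genes at 8 h (n = 4 and 2). Exoc4 (chr6:33249085-33973979), which encodes a subunit of the exocyst, rose from 955 to 5809 CPM (log2 2.68, SE 0.51, adjusted p = 0.00377, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Myo1e, a myosin gene, gave 109 UMIs against 1 (a ratio of 25.5, 4.47 to 1015). Ccnd3 (chr17:47505051-47599691), which encodes cyclin D3, fell from 2242 CPM (SD 701) to 492 CPM (SD 500, adjusted p = 0.0197 by edgeR). All 3 lay without overlap, where 13.3% of unselected genes would by chance, and DESeq2 called 3. The count was 1 without 8 h tumour 1 or 8 h tumour 2 and 8 without unirradiated brain 1. Exoc4 kept its call in 5 of 6 fits with a specimen left out, Myo1e in 3 and Ccnd3 in 2. At 72 h (n = 2 and 2) 0 genes passed, 13 had an unadjusted p under 0.05, and DESeq2 called 0. Without unirradiated brain 1 the count at 72 h was 7. Microglia markers had a median of -0.86 at 72 h (adjusted p = 0.000889 by camera; adjusted p = 0.0469 with an estimated correlation), with Cst3 at -2.39 and C1qa at -1.49.

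Oligodendrocyte-like cells gave 0 called genes at 8 h and at 72 h (n = 3 and 3 each). Of 423 genes tested, 51 and 25 had an unadjusted p under 0.05, and DESeq2 called 0 and 0. Without unirradiated tumour 3 the counts were 8 and 3, and without 8 h brain 2 the count at 8 h was 6. Among the smallest p values at 8 h were those of Nav3 (2.39), Zbtb16 (-2.36), Exoc4 (1.80) and Fhit (-2.11), none of which passed (adjusted p = 0.143 by edgeR). At 72 h Fhit stood at -2.27 and Atp8a1 at -1.24 (adjusted p = 0.510 by edgeR), again without passing. The myelin list stood at -0.02 and -0.13 (adjusted p = 0.403 and 0.458 by camera).

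In the mixture of human 293T and mouse NIH3T3 cells, 553 cells were human, 829 mouse and 59 mixed. The mixed share was 4.09% (95% exact binomial interval 3.13 to 5.25%), which implies 8.53% of barcodes with 2 cells when pairs of the same species are counted too. The median was 2270 UMIs per cell of this mixture. At a purity of 80% the mixed share was 3.40%.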

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

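The tests of RT wells, also against a difference of 1 specimen, of left-out specimens with an estimated correlation and of free RNA were chosen after the results were seen, and the other tests in this part were written down before. The first result flagged for a closer look was the p53 target list at 8 h, whose effect in tumour exceeded that in brain by a median log2 difference of 2.01 in a test of that difference. The second was 4930579P08Rik at 72 h, whose effect in tumour exceeded that in brain by log2 9.95 in the same kind of test. Both are differences between whole specimens, which also held different cell types.

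The rise of p53 targets in 8 h tumours was weighed against 3 technical explanations. A higher share of OPC/tumour-like cells would raise OPC identity genes too, but their median log2 fold change was 0.36 against 2.14 for p53 targets. With any 1 specimen left out, the largest adjusted p of the list by camera was 1.03e-25 in whole tumours and 1.97e-23 in OPC/tumour-like cells. With an estimated correlation the largest was 0.0186 in whole tumours, whereas in OPC/tumour-like cells the list did not pass with all specimens (adjusted p = 0.0634) or with any left out (highest 0.391). Of the 9 called p53 targets 0 were single-well genes. These values argue against the 3 explanations, as worded, in whole tumours. OPC identity genes cannot show a shift between the clusters of the OPC/tumour-like class. Cluster 1 held 30.7% of that class in unirradiated tumours and 84.2% in 8 h tumours, and whether this played a part was not tested. The planned test of the library pool, the list with pool A alone (adjusted p = 4.87e-44 by camera), was void, since both groups lie wholly in that pool. Irradiation is what the design varies, but with 2 irradiated tumours another difference between the specimens could also play a part.

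The fall of 4930579P08Rik, Kyat3 and Hsf2bp in irradiated brain, and with it the 72 h difference of 9.95, came from unirradiated brain 1. At least 98.2% of the UMIs of each gene in that specimen lay in 1 of its 12 RT wells, which fits an RT well artefact. A test of a specimen difference by the smallest ratio to the next brain gave 4.50 and did not decide. That ratio, of Kyat3, rests on 1 UMI in 72 h brain 3 (79.2 CPM), and the next, 5.39 for Hsf2bp, on 57 UMIs. A difference of the whole specimen would spread over its wells, but at most 1.83% of the UMIs of a gene lay outside its top well, which held 11.8% of the cells or fewer. Whether irradiation acts on these genes cannot be told from these specimens.

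The mouse matrix ends in a feature named for a long terminal repeat (LTR), the end of a retroviral genome, though what it was built from is not given in the sources used here. It was seen in 684 of 5316 OPC/tumour-like cells of tumours (12.9%, median 392.5 UMIs per cell) and in 0 of 165 such cells of brain. Of 1992 neuron-like cells of tumours 1.26% held it (median 1254 UMIs), which gauges free RNA. Differentiating oligodendrocyte-like cells held it in 9.41% (median 759 UMIs), at 22.9 times the neuron-like level in CPM (95% interval 13.3 to 39.4), which argues against free RNA alone, though 12 of the 56 such cells of 8 h tumour 1 held it and 4 of the 125 of 72 h tumour 1. Oligodendrocyte-like cells of tumours stood higher in CPM (213 against 175), from 5 of 138 cells, and whether doublets with tumour cells could give either level was not tested. In neuron-like cells the LTR feature stood at 18.9 and 34.3 CPM in 8 h tumours (19 and 2 UMIs). It stood at 0, 0 and 2.59 CPM in unirradiated tumours (0, 0 and 3 UMIs).

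Group labels were swapped between specimens to ask how often chance gives as many genes. This was not done for tumour at 8 h or 72 h, brain at 8 h or the differences between tissues. Nor was it done for OPC/tumour-like or microglia/macrophage-like cells. Between tumour and brain, 2 of 100 splits gave as many genes as the real 1445, the real one included. So large a count was rare by chance, but another split gave more, so chance is not excluded. The highest other split gave 1932 and swapped 72 h brain 3 with 72 h tumour 2, both of pool B, and that tumour held 1 OPC/tumour-like cell of 483. Among neuron-like cells chance cannot be excluded, since 11 of 100 splits at 8 h and 29 of 100 at 72 h gave as many genes as the real 6 and 6, with highest others of 12 and 37.

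For 4 comparisons only 10 splits existed, too few to tell. Without irradiation 4 of 10 gave as many genes between tumour and brain as the real 4, and the highest other, 570, swapped unirradiated brain 1 with unirradiated tumour 1. A split that calls so many more genes points to a structure among these specimens that the groups do not describe. For brain at 72 h 7 of 10 gave as many as the real 2, with a highest other of 3. For oligodendrocyte-like cells the test was void, since the real count was 0 at 8 h and at 72 h and any split gives as many (10 of 10 each, with a highest other of 1 each).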

How the results depend on the processing

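The settings without single-well genes, without the 2 specimens of the 72 h groups in pool B, without the 3 Xist specimens, without a pool term while leaving out a specimen, and the p53 list with each specimen left out were chosen after seeing the data. The cause of a change was not tested unless stated. Values are numbers of genes called by edgeR. Over all settings 117 results moved and 1 was weaker. The other counts gave an equal or similar total, which need not be the same genes or directions. The p53 list otherwise kept its direction and its side of the threshold.

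With DESeq2 the counts became 130 for tumour against brain without irradiation, 80 for tumour at 8 h, 16 for tumour at 72 h, 4 for brain at 72 h, 5 and 2 for the difference between tissues at 8 h and 72 h, 8 for OPC/tumour-like cells at 72 h, and 0 and 3 for neuron-like cells at 8 h and 72 h. DESeq2 size factors in edgeR gave 3 for neuron-like cells at 8 h. Without the low-count filter the difference between tissues at 8 h gave 1, OPC/tumour-like cells 139 and 71, neuron-like cells 14 and 11, oligodendrocyte-like cells 7 and 6, and microglia/macrophage-like cells at 8 h 0. Without single-well genes the counts were 0 for tumour against brain without irradiation, 0 and 0 for brain at 8 h and 72 h, 0 for the difference at 72 h, and 1 and 3 for neuron-like cells. In brain this follows by construction, but between tissues without irradiation and in neuron-like cells at 8 h other genes lost their call too.

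Without a pool term the counts were 162 for tumour against brain without irradiation, 0 and 0 for brain, 0 for the difference at 72 h, and 2 for neuron-like cells at 8 h. With pool A alone, and so fewer specimens, they were 922 for tumour against brain, 1 without irradiation, 25 for tumour at 8 h, 1 for tumour at 72 h and 1 for the difference at 8 h. Fits of only the groups compared gave 1 without irradiation, 0 for tumour at 8 h, 34 and 5 for brain, and 1 and 0 for the difference. Without the 2 pool B specimens of the 72 h groups, tumour at 72 h gave 1. Without a pool term and without 72 h tumour 1, tumour against brain gave 12. Without the 3 Xist specimens it gave 805. That setting leaves out 8 h tumour 1 and so leaves 1 tumour at 8 h, and its count for tumour at 8 h is not given. OPC/tumour-like cells without the cycling cluster gave 6 at 72 h.

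The labels number the specimens of each group, and a replicate block on these numbers gave 100 without irradiation, 17 for tumour at 8 h and 43 for tumour at 72 h. Residual correlations of like-numbered specimens ran from -0.257 to 0.196 within a tissue, where 2 of 13 pairs exceeded 0.1. Between tumour and brain they ran from -0.081 to 0.066. No pairing was seen, but groups this small cannot exclude one. By Xist and Y-linked UMIs, 8 h tumour 1 (3117 and 11) and 8 h brain 1 (1 and 1037) differed in sex, which argues against that pair.

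Of 51 pathway list calls in whole specimens 2 were left with an estimated correlation and 11 by fry, of 8 in OPC/tumour-like cells 0 and 1, and of 6 in other classes 0 and 0. Without a pool term camera lost 12 list calls of whole specimens and gained 4, and with pool A alone it lost 8 and gained 6. Without the term the losses were immediate early genes between tissues, these with heat shock and hypoxia between tissues without irradiation, heat shock and the interferon response in tumour at 72 h, hypoxia and synaptic genes in brain at 72 h, OPC identity in the difference at 8 h, and heat shock, hypoxia and immediate early genes in that at 72 h. With pool A they were the interferon response, OPC identity and synaptic genes in tumour at 72 h, synaptic genes in brain at 72 h, OPC identity in the difference at 8 h, and OPC identity, proneural glioma and synaptic genes in that at 72 h. The p53 list in OPC/tumour-like cells at 8 h was weaker with an estimated correlation (adjusted p = 0.0634). At a purity of 95% the mixed share of the species mixture was 8.61%.

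Leaving out each specimen gave 0 to 2913 for tumour against brain, 0 to 979 without irradiation, 20 to 1194 for tumour at 8 h, 0 to 383 for tumour at 72 h, 0 to 4 and 0 to 2 for brain, and 0 to 195 and 0 to 6 for the difference. In OPC/tumour-like cells it gave 9 to 39 and 0 to 15, in neuron-like cells 2 to 14 and 5 to 13, in oligodendrocyte-like cells 0 to 8 and 0 to 3, and in microglia/macrophage-like cells 1 to 8 and 0 to 7. Class shares that passed ran from 0 to 1 by time and from 2 to 3 between tissues. The p53 list at 8 h kept adjusted p from 3.26e-40 to 1.03e-25 in whole tumours and from 3.58e-35 to 1.97e-23 in OPC/tumour-like cells. The same fits with an estimated correlation gave 0.000374 to 0.0186 and 0.0884 to 0.391. Where this left 1 specimen in a group, that lone specimen is assumed to vary like the other groups.

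Not run were astrocyte-like cells at either time, oligodendrocyte-like and microglia/macrophage-like cells with at least 50 cells, and OPC/tumour-like cells at 72 h without 72 h tumour 1, for lack of cells. Depth limits the scarce specimens, with 12627 UMIs in 72 h brain 3 and 95688 in unirradiated tumour 2. In simulated data at a 4-fold change the fit of whole specimens missed many genes (123 of 200 found), so a count of 0 does not exclude changes.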

Other observations

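The OPC/tumour-like contrast of 72 h with 8 h was planned, and Exoc4 was chosen after its values were seen. Exoc4, a subunit gene of the exocyst, rose at 8 h in whole tumours (log2 2.41, adjusted p = 0.00521), in OPC/tumour-like cells (2.88, adjusted p = 0.0109) and in microglia/macrophage-like cells (2.68, adjusted p = 0.00377, all by edgeR). In oligodendrocyte-like cells it stood at 1.80 (adjusted p = 0.143 by edgeR), in neuron-like cells at 0.49 (unadjusted p = 0.0619 by edgeR) and in whole brain at 0.40 (unadjusted p = 0.368 by edgeR). The call in OPC/tumour-like cells was kept in only 2 of 5 fits with a specimen left out. At 72 h it stood at 0.68 in whole tumours, 1.76 in OPC/tumour-like cells, 1.88 in microglia/macrophage-like cells and 0.94 in oligodendrocyte-like cells, without passing. The difference between tumour and brain at 8 h was 2.01 and did not pass (adjusted p = 0.752 by edgeR).

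In OPC/tumour-like cells the cycling cluster held 1.09%, 16.5% and 2.04% of cells in unirradiated tumours, 6.41% and 21.1% at 8 h, and 12.3% in 72 h tumour 1. The LTR feature stood at 706, 178 and 44.8 CPM in unirradiated tumours, 186 and 386 CPM at 8 h, and 14.3 and 0 CPM at 72 h. Brains held between 0 and 16.5 CPM of it.

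The hypothesis that p53 targets in OPC/tumour-like cells had fallen again by 72 h could not be decided, since 1 specimen stood for 72 h. In the contrast of 72 h with 8 h the list had a median log2 difference of -1.84 and p = 2.19e-16 by camera (adjusted p = 0.123 with an estimated correlation). The cells compared differed too, since cluster 11 held 76.6% of the class at 72 h and 2.0% in 8 h tumours. The LTR feature stood at 77.5 CPM in these cells of 72 h tumour 1, against 258 and 523 CPM in those of the 8 h tumours.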
